A study of Homo sapiens with 4 samples.

How the data were processed

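The series holds 4 TT-seq libraries of untreated K562 cells, 2 after 5 min and 2 after 15 min of labelling with 4-thiouridine. Per the labels' protocols, a fixed mass of total RNA was mixed with a fixed mass of Drosophila S2 RNA, sheared by sonication, biotinylated at thiol groups and enriched on streptavidin beads before sequencing. Per the submitters' processing notes, the tools were bcl2fastq 2.17.1.14, STAR 2.7, featureCounts with Subread 2.0.1 and edgeR (no version given), and the genome builds were hg38 and dm6. The notes give no role or order for these tools. The counting feature and strand setting are not given in the sources used here, so counts of genes that overlap other genes or lie in their introns are uncertain. Such genes were kept in all tests.

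The authors deposited raw read counts per human gene and per fly gene for each library, as whole numbers that were not normalized. The authors also deposited 1 production rate per gene for the untreated cells, used here as a score because per the file headers it is a synthesis rate and no scale, time unit or method is given. It is a single value per gene and carries no replicate error. The libraries and label times behind it are not given in the sources used here. All deposited columns could be tied to a library by name.

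The human counts held 60279 gene identifiers, of which 56590 were found in GENCODE 29, an annotation of the same human build, which gave symbols, gene types, positions and exonic lengths. Of 17322 tested genes, 17101 were in that annotation. The rates table pairs identifiers with symbols, and these were used for list matching as well. The 17807 fly identifiers were used as given, since the tables used here do not pair them with names.

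Depth was 4339981 to 5051370 human reads and 308978 to 897018 fly reads per library. Between 26824 and 27872 human genes had at least 1 read. Within each label time the libraries differed by more than sampling noise (chi-square per degree of freedom 1.70 over genes for 15 min and 1.55 for 5 min) and were counted as separate samples. The correlation of log2 CPM was 0.988 between the 15 min libraries, 0.986 between the 5 min libraries, and 0.97 and 0.969 between label times for replicates 1 and 2. Counting intervals and the counts themselves cover sampling of reads only, since no molecular identifiers are given.

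The choices below were made before the data were examined unless stated otherwise. Labelled yield was the ratio of human to fly reads per library, compared by an exact permutation test. Share of the labelled RNA was tested with edgeR 4.0.16 (filterByExpr defaults with a minimum count of 10, TMM factors, robust quasi-likelihood fit) with label time as the only term, and accumulation was tested in the same way with library sizes set to the fly read totals and no TMM factor. P-values were two-sided and adjusted by the Benjamini-Hochberg method at 0.05, and standard errors were taken from the quasi-likelihood F statistic. Gene lists with at least 5 measured members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, and again with an estimated correlation, which leaves the test with 2 residual degrees of freedom. With a preset correlation 18 of 23 lists passed, 3 higher and 15 lower, and with an estimated correlation 0 passed. For the rates, the median of a list was placed among 10000 random lists of the same size.

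The lists, fixed before the data were examined, were globin and erythroid genes, immediate early and short-lived regulators, ribosomal protein genes, mitochondrially encoded genes, snoRNA host genes, transcription elongation and bromodomain factors, mRNA decay factors, BCR-ABL signalling genes, apoptosis regulators, leukaemia oncogenes and haematopoietic transcription factors, glycolysis genes, nuclear encoded oxidative phosphorylation genes, heat shock genes, integrated stress response genes, S phase and replication genes, G2 and mitosis genes, cholesterol synthesis genes, spliceosome genes, ribosome biogenesis and MYC target genes, enhancer and nuclear noncoding RNA genes, genes spanning very long loci, replication-dependent histone genes, and markers of T cells, B cells, monocytes and macrophages, fibroblasts and epithelial cells. Some genes stand in more than 1 list, such as MYC and PIM1.

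Named genes followed a rule. For the share of labelled RNA they were the 10 largest gains and the 10 largest losses among genes with an adjusted p under 0.05, an average log2 CPM of at least 3 and both 15 min libraries on the same side of both 5 min libraries, with genes that have no symbol left out. For each list they were the 3 members with the highest mean CPM, and for a list that passed also the 2 members with the smallest p in its direction. For the rates they were the 10 highest and the 5 lowest among genes with an average log2 CPM of at least 3. Members of the mitochondrial list that did not pass, MT-CO3, the genes that fell on the spike-in scale and genes with no rate or no reads were named after their values were seen. Some genes that the rule takes are not reported here.

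The share test was tested on simulated data with the real means and library sizes, in which 200 of 16934 genes were changed. It recovered 23.9% of genes changed 1.25-fold, 46.3% of those changed 1.5-fold and 78.8% of those changed 2-fold, with 8 false calls among 107. A simulated shifted list was called, and 0 of 19 unshifted lists were. Genes were simulated independently of each other, so this does not test lists whose members vary together. Estimated correlations in the real lists ran from -0.022 to 0.864. Alternatives were RLE factors, total-count scaling, other filters, DESeq2 1.42.0, limma-voom, a replicate block, leaving out mitochondrial genes or each library in turn, other spike-in factors, fry, and other backgrounds for the rates. Medians of lists and gene types under total-count scaling were added after the data were seen. Scripts ran in R 4.3.3 and Python 3.11.15 with scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.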

Results

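Newly made RNA was measured in untreated K562 cells, an established chronic myeloid leukaemia line that carries the BCR-ABL fusion and has erythroid features. The assay was transient transcriptome sequencing (TT-seq), in which cells take up 4-thiouridine for a few minutes, and the RNA made in that time is biotinylated through its thiol group and enriched on streptavidin beads. Cells were labelled for 5 min or for 15 min, with 2 libraries at each label time, and a fixed mass of Drosophila S2 cell RNA was added to a fixed mass of total RNA from every sample before enrichment. The human gene counts summed to 5051370 and 4726327 reads in the 15 min libraries and to 4339981 and 4695405 reads in the 5 min libraries. The fly gene counts summed to 318710 and 308978 reads after 15 min and to 897018 and 803914 reads after 5 min. A table of production rates, with 1 value per gene for the untreated cells, was deposited with the counts, and the series was made to obtain these rates. The sources used here do not say whether the 2 libraries of a label time came from separate cultures. P-values therefore measure only the spread between these libraries, which may be technical. The edgeR fit estimates that spread partly from all genes together. An SE can thus be smaller than the 2 libraries of a gene alone would give.

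The first comparison asked how much labelled human RNA each label time gave relative to the fly RNA, which measures yield per mass of total RNA. The 15 min libraries held 15.6 ± 0.391 human reads per fly read and the 5 min libraries 5.34 ± 0.709 (mean ± SD, n = 2 each). The ratio of the means was 2.92 with a propagated SD of 0.394, and the 4 pairings of a 15 min with a 5 min library gave 2.62 to 3.28. The ratio of the label times themselves was 3. Genes encoded in the mitochondrial genome took 6.43% ± 0.715 of the human reads after 15 min and 2.33% ± 0.368 after 5 min (SD, n = 2 each). A two-sided exact permutation test of human reads per fly read gave p = 0.333, which is the smallest p that the 6 arrangements of 4 libraries allow, so this design could not pass a threshold of 0.05.

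**Figure D1:**
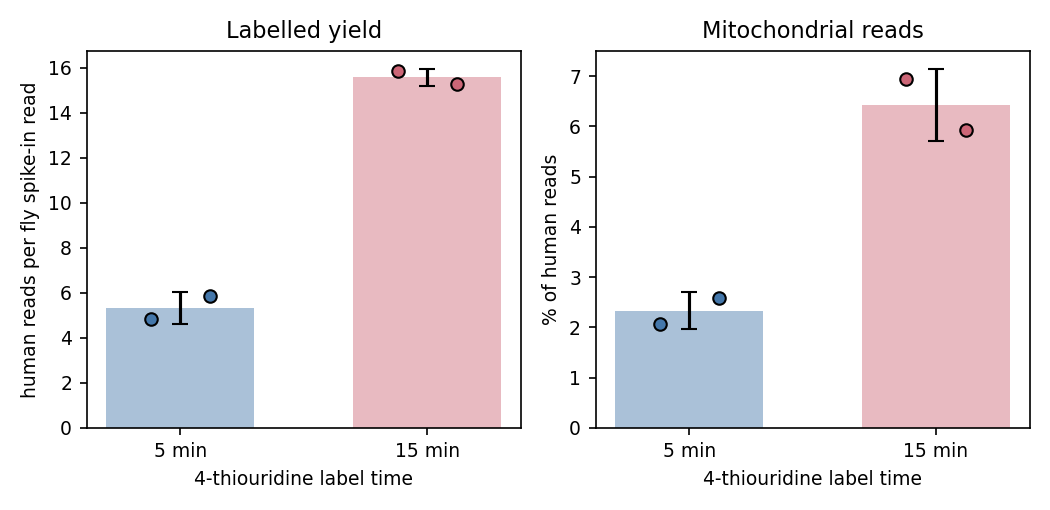
Human reads per fly spike-in read (left) and percent of human reads on mitochondrially encoded genes (right) after 5 and 15 min of labelling. Points are libraries, bars are means of 2 libraries and error bars are SD. Human reads per fly read averaged 5.34 after 5 min and 15.6 after 15 min, and the mitochondrial share averaged 2.33% and 6.43%.

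The second comparison asked which genes accumulated labelled RNA between 5 and 15 min on the scale set by the fly reads. Labelled RNA of 17041 of 17322 tested genes rose, with a median fold of 3.20. All these calls rest on the same fly totals. An error in that scale would move every gene together, which p-values per gene do not measure. The genes of the oncogenic transcription factors MYC and MYB rose by 3.63- and 3.24-fold. Mitochondrially encoded genes rose most among the lists, with a median fold of 9.66 over 15 genes (14 rose), and ranged from 4.30-fold for MT-CO3 to 12.5-fold for MT-ND2 among the protein-coding members. Glycolysis genes had the lowest list median, 1.84-fold over 23 genes, all of which rose, with GAPDH at 1.48-fold and ALDOA at 1.46-fold. The gamma-globin gene HBG2, at 1.15-fold (adjusted p = 0.238), and the epsilon-globin gene HBE1, at 1.13-fold (adjusted p = 0.302), did not pass the test.

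Over all tested genes, the 5th and 95th percentiles of the spike-in scaled fold were 1.85 and 5.72, the quartiles were 2.57 and 4.01, and 58.1% of the genes lay above 3-fold. Other list medians were 3.99-fold for immediate early and short-lived regulators (55 of 55 rose) and 3.99-fold for snoRNA host genes (24 of 24 rose). They were 2.48-fold for globin and erythroid genes (41 of 46 rose), 2.44-fold for ribosomal protein genes (79 of 79) and 2.27-fold for nuclear encoded oxidative phosphorylation genes (63 of 65). Only 2 genes fell. RN7SK, the 7SK RNA that holds the elongation factor P-TEFb in an inactive complex, fell to 0.599 of its 5 min level (log2 fold change -0.74 ± 0.194 SE, adjusted p = 0.000162). SCARNA5, a small Cajal body RNA nested in ATG16L1, fell to 0.634 (log2 fold change -0.66 ± 0.258 SE, adjusted p = 0.0113). The tests were edgeR quasi-likelihood tests with library sizes set to the fly read totals and Benjamini-Hochberg adjustment. With DESeq2 both of these falls missed the threshold (log2 fold change -0.74, adjusted p = 0.157 for RN7SK and -0.67, 0.116 for SCARNA5). Without replicate 1 of the 15 min group they were -0.37 (adjusted p = 0.395) and -0.59 (0.152), and without replicate 2 of the 5 min group -0.40 (0.679) and -0.12 (0.656). Without replicate 1 of the 5 min group they were -1.01 (0.398) and -1.07 (1.41e-05), and without replicate 2 of the 15 min group -1.24 (0.00534) and -0.74 (0.076).

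**Figure D2:**
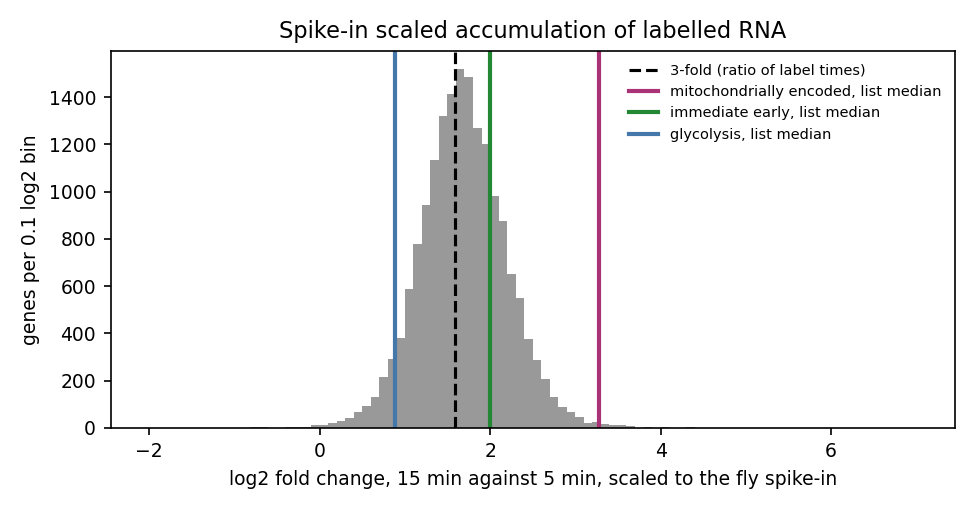
Number of genes by log2 fold change of labelled RNA, 15 min against 5 min, scaled to the fly spike-in reads (17322 tested genes, bins of 0.1). The dashed line marks 3-fold, the ratio of the label times, and coloured lines mark list medians, which were 1.84-fold for glycolysis genes, 3.99-fold for immediate early and short-lived regulators and 9.66-fold for mitochondrially encoded genes.

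The third comparison asked which genes gained or lost share of the labelled RNA once the common rise was taken out by scaling each library to its own human reads (TMM factors). Gains and losses were ranked among genes that passed with an average log2 CPM of at least 3 and libraries separated by label time. Between 5 and 15 min, the largest gains in this set were mostly those of mitochondrial genome genes, which encode subunits of the respiratory chain. The largest losses in the set were seen for nuclear genes that included SCARNA5, CFD (complement factor D), TPMT (thiopurine methyltransferase), BST2 (tetherin) and HSPG2 (perlecan). MT-ND2, a subunit of complex I, rose from 1265 ± 226 to 5092 ± 737 CPM (reads scaled to a library size of 1000000, mean ± SD, n = 2 each). Its log2 fold change was 2.01 ± 0.0737 (SE, adjusted p = 6.07e-55), and 1.81 to 2.19 over the alternatives. HSPG2 fell from 233 ± 6.05 to 79.7 ± 13.3 CPM, a log2 fold change of -1.55 ± 0.0734 (adjusted p = 4.11e-95). Immediate early and short-lived regulators and snoRNA host genes gained share as groups, and globin, ribosomal protein, glycolysis, oxidative phosphorylation, heat shock and cell cycle genes lost share. These calls rest on a preset correlation between genes, and with an estimated correlation 0 of 23 lists passed.

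In all, 6607 of 17322 tested genes changed in share, 2915 higher and 3692 lower after 15 min, and of these 467 were more than 2-fold higher and 333 more than 2-fold lower. Both 15 min libraries lay on the same side of both 5 min libraries for 67.6% of the genes, where chance gives 33.3%. The biological coefficient of variation between libraries of a label time was 4.08%. Scaling to total counts moved the median log2 fold change of all genes from 0.03 to 0.13 and gave 4253 higher and 2792 lower, 60.4% higher in place of 44.1%, so that directions close to 0 depend on the scaling. DESeq2 called 3293 genes, 923 higher and 2370 lower, and without replicate 1 of the 15 min group or replicate 2 of the 5 min group 1795 and 1729 genes were higher.

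Of the 10 genes with the largest gains among those of moderate or high level, 6 lay on the mitochondrial chromosome: MT-ND2, MT-ND4L, MT-ND1, MT-ATP8, MT-ATP6 and MT-ND5. MT-ND1 (chromosome M, 3307 to 4262) rose by 1.84 on the log2 scale, MT-ATP8 (8366 to 8572) by 1.83, MT-ND4L (10470 to 10766) by 1.84 and MT-ND5 (12337 to 14148) by 1.65. MT-ATP8 shares bases with MT-ATP6, and MT-ND4L with MT-ND4, so their values are not independent. Another 3 were nuclear copies of mitochondrial genes. MTATP6P1 on chromosome 1 (log2 fold change 1.88), MTND4P12 on chromosome 5 (1.77) and MTCYBP18 on chromosome 5 (1.77) are near-identical to mitochondrial genes, and their counts are uncertain because reads can be shared. MTCYBP18 had 8 and 24 reads after 5 min, and its log2 fold change was 1.20 without replicate 1 of that group and 2.697 without replicate 2. The remaining gene was IPO4, which encodes an importin, on chromosome 14 (4.07 ± 1.00 to 13.1 ± 1.00 CPM, log2 fold change 1.68 ± 0.265 SE, adjusted p = 2.96e-09). IPO4 overlaps REC8 on the other strand and the coding gene AL136295.4 on its own strand, so its count is uncertain whatever the strand setting of the counting, which is not given in the sources used here.

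Among the 10 genes with the largest losses, SCARNA5 on chromosome 2 fell from 26.3 ± 8.77 to 5.38 ± 0.521 CPM (log2 fold change -2.29 ± 0.205 SE, adjusted p = 4.13e-27). CFD fell by 1.84 on the log2 scale (14.3 ± 0.329 to 3.99 ± 0.459 CPM), TPMT by 1.64 (37.8 ± 8.25 to 12.1 ± 0.866 CPM), and the long noncoding RNA LINC00641 by 1.64 (74.5 ± 1.75 to 23.9 ± 2.19 CPM). RIDA, which encodes an imine deaminase, fell by 1.67, BST2 by 1.58, and STMN3, a stathmin family gene, by 1.56. AC245297.1, annotated as an unprocessed pseudogene, fell by 1.69, and RPS2P5, a processed pseudogene of the ribosomal protein gene RPS2, fell by 1.55. The counts of both pseudogenes are uncertain because reads can be shared with near-identical copies. RN7SK went from 6599 ± 1143 to 1282 ± 557 CPM, a log2 fold change of -2.37 ± 0.505 (SE) that did not pass (adjusted p = 0.0955, with 0.392 the highest and 6.66e-315 the lowest over the alternatives).

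Mitochondrially encoded genes gained share as a group, with 11 of 15 measured members higher and none lower (12 higher adjusted over the list alone) and a median log2 fold change of 1.64 (camera adjusted p = 1.11e-07, adjusted p = 0.323 with an estimated correlation). MT-CYB rose by 1.42, MT-ND4 by 1.64 and MT-CO1 by 0.64 on the log2 scale. The members that did not pass were MT-ND3 (log2 fold change 1.88, adjusted p = 0.0608), MT-ND6 (1.40, adjusted p = 0.128) and the ribosomal RNA genes MT-RNR1 (0.91, adjusted p = 0.612) and MT-RNR2 (0.63, adjusted p = 0.48). Of 55 immediate early and short-lived regulators, whose mRNAs decay quickly, 33 rose and 1 fell (36 and 1 adjusted over the list alone). The median was 0.34 (camera adjusted p = 1.03e-06, adjusted p = 0.224 with an estimated correlation). The phosphatase gene DUSP1 rose by 0.98 and PPP1R15A, which encodes a phosphatase regulatory subunit of the stress response, by 0.88 on the log2 scale. PIM1 had a log2 fold change of 0.03 (adjusted p = 0.731). MYC rose by 0.22 (453 ± 12.1 to 526 ± 8.27 CPM, adjusted p = 0.00158), a call lost without replicate 1 of the 5 min group (adjusted p = 0.0985) and without replicate 2 of the 15 min group (adjusted p = 0.0626). Of 24 snoRNA host genes, which carry small nucleolar RNAs in their introns, 15 rose and 1 fell (15 and 1 adjusted over the list alone). The median was 0.34 (camera adjusted p = 0.00207, adjusted p = 0.341 with an estimated correlation). GAS5 rose by 0.32, SNHG1 by 0.42 and SNHG7 by 0.94 on the log2 scale, SNHG3 had a log2 fold change of 0.03 (adjusted p = 0.718), and SNHG7 is annotated as antisense to a coding gene, so its count is uncertain.

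Globin and erythroid genes lost share, with 24 of 46 lower and 2 higher (24 and 2 adjusted over the list alone) and a median of -0.34 (camera adjusted p = 2.61e-06, adjusted p = 0.224 with an estimated correlation). HBG2 fell from 480 ± 76.0 to 177 ± 11.8 CPM (log2 fold change -1.44 ± 0.0633 SE), although its count can be shared with the near-identical HBG1, HBE1 fell by 1.47 and the transferrin receptor gene TFRC by 0.37. Ribosomal protein genes were lower in 59 of 79 cases and higher in 8 (59 and 8 adjusted over the list alone). The median was -0.36 (camera adjusted p = 1.66e-09, adjusted p = 0.31 with an estimated correlation). RPL8 fell by 1.12, RPS21 by 1.08 and RPL37 by 0.37. Of 23 glycolysis genes 19 fell and 2 rose (19 and 2 adjusted over the list alone). The median was -0.76 (camera adjusted p = 7.9e-07, adjusted p = 0.224 with an estimated correlation). GAPDH fell from 701 ± 28.7 to 332 ± 28.2 CPM, LDHB by 1.15 on the log2 scale and ENO1 by 0.87. Nuclear encoded oxidative phosphorylation genes moved the opposite way to the mitochondrially encoded ones, with 44 of 65 lower and 2 higher (47 and 2 adjusted over the list alone) and a median of -0.46 (camera adjusted p = 1.66e-09, adjusted p = 0.224 with an estimated correlation). The ATP synthase genes ATP5F1B and ATP5F1C each fell by 1.05 on the log2 scale.

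Heat shock genes were lower in 20 of 32 cases and higher in 3 (22 and 3 adjusted over the list alone). The median was -0.41 (camera adjusted p = 1.93e-05, adjusted p = 0.31 with an estimated correlation). The chaperone genes HSP90AA1 and HSP90AB1 fell by 1.05 and 0.89. Among 47 S phase and replication genes, 25 fell and 1 rose (25 and 1 adjusted over the list alone). The median was -0.23 (camera adjusted p = 6.77e-05, adjusted p = 0.224 with an estimated correlation). The replicative helicase genes MCM7 and MCM4 each fell by 0.37. Among 43 G2 and mitosis genes, 34 fell and 0 rose (36 and 0 adjusted over the list alone). The median was -0.38 (camera adjusted p = 2.48e-09, adjusted p = 0.26 with an estimated correlation). TOP2A fell by 0.97, TPX2 by 0.87 and MKI67 by 0.40. Of 51 replication-dependent histone genes, 22 fell and 0 rose (24 and 0 adjusted over the list alone). The median was -0.19 (camera adjusted p = 0.000284, adjusted p = 0.548 with an estimated correlation). The mean log2 fold change of the list lay 0.31 below that of other genes, and 0.19 below without replicate 1 of the 15 min group (adjusted p = 0.0234). HIST1H1C fell by 0.63. Histone genes form a multigene family, and reads may be split among its members. Cholesterol synthesis genes were lower in 15 of 25 cases and higher in 2 (17 and 2 adjusted over the list alone). The median was -0.30 (camera adjusted p = 0.000138, adjusted p = 0.266 with an estimated correlation). DHCR7, the last enzyme of the pathway, fell by 0.92.

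Spliceosome genes fell in 38 of 57 cases and rose in 4 (39 and 6 adjusted over the list alone). The median was -0.33 (camera adjusted p = 1.07e-06, adjusted p = 0.224 with an estimated correlation). PRPF8 fell by 0.93 and SNRPD2 by 1.17. Of 50 ribosome biogenesis and MYC target genes, 23 fell and 6 rose (25 and 7 adjusted over the list alone). The median was -0.17 (camera adjusted p = 0.00435, adjusted p = 0.224 with an estimated correlation). BOP1 fell by 1.30 and NPM1 by 0.54, whereas nucleolin (NCL) had a log2 fold change of -0.10 (adjusted p = 0.188). Of 38 BCR-ABL signalling genes, 19 fell and 3 rose (20 and 3 adjusted over the list alone). The median was -0.24 (camera adjusted p = 0.00091, adjusted p = 0.232 with an estimated correlation). The transcription factor genes STAT5B and STAT5A fell by 1.01 and 0.71. Among 64 mRNA decay factors, 24 fell and 6 rose (25 and 6 adjusted over the list alone). The median was -0.13 (camera adjusted p = 0.012, adjusted p = 0.224 with an estimated correlation). The deadenylase scaffold gene CNOT1 fell by 0.85. Genes spanning very long loci were lower in 9 of 32 cases and higher in 3 (9 and 3 adjusted over the list alone). The median was -0.15 (camera adjusted p = 0.0364, adjusted p = 0.266 with an estimated correlation). BIRC6 fell by 0.51 and NBAS by 0.53. Camera set each list against all other tested genes, noncoding ones included. Of 11547 protein-coding genes, 3519 fell and 1586 rose, with a median of -0.08. The lists of mRNA decay factors and very long loci thus lay close to protein-coding genes in general. Under total-count scaling the list medians shrank to -0.03 for mRNA decay factors, -0.05 for very long loci, -0.06 for ribosome biogenesis genes and -0.08 for histone genes. They were -0.13 for BCR-ABL signalling genes and for S phase genes and -0.19 for cholesterol synthesis genes.

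The other lists did not pass the camera test. Transcription elongation and bromodomain factors, the class to which inhibitors of transcription are directed, had 18 of 45 members lower and 6 higher (18 and 6 adjusted over the list alone), with a median of -0.08 that became 0.03 under total-count scaling (camera adjusted p = 0.0581). BRD2 rose by 0.57 on the log2 scale, and AFF1 (0.03, adjusted p = 0.782) did not pass. Leukaemia oncogenes and haematopoietic transcription factors had 6 of 27 members higher and 6 lower (6 and 6 adjusted over the list alone), with a median of -0.06 that became 0.05 under total-count scaling (camera adjusted p = 0.478), and ZEB2 rose by 0.27. Apoptosis regulators had 4 of 32 members higher and 6 lower (3 and 6 adjusted over the list alone), with a median of 0.001 and a mean of 0.02, while camera ranked them lower (adjusted p = 0.957), and MCL1 had a log2 fold change of -0.02 (adjusted p = 0.811). Integrated stress response genes had 14 of 35 members higher and 12 lower (14 and 12 adjusted over the list alone). Their median was 0.07 and their mean -0.003. Camera, which compares gene statistics and not medians, ranked them higher (adjusted p = 0.899). ATF4 and VEGFA rose by 0.46 and 0.57. Enhancer and nuclear noncoding RNA genes had 5 of 20 members higher and 4 lower (5 and 4 adjusted over the list alone), with a median of 0.06, a mean of -0.02 and a camera result in the direction of the median (adjusted p = 0.871). MALAT1 fell by 0.48, from 7648 ± 279 to 5471 ± 102 CPM, and MIR17HG, the host of a microRNA cluster, had a log2 fold change of 0.10 (adjusted p = 0.197). By annotation HSPG2, GAS5, BRD2, AFF1, CNOT1, HSP90AA1, MCM7, SNRPD2, BOP1, HBG2 and HBE1 overlap a coding gene on the other strand. HBG2 and HBE1 also overlap each other on the same strand, and SNHG3, ALDOA and LDHB overlap a coding gene on theirs, so the counts of these genes are uncertain.

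**Figure D3:**
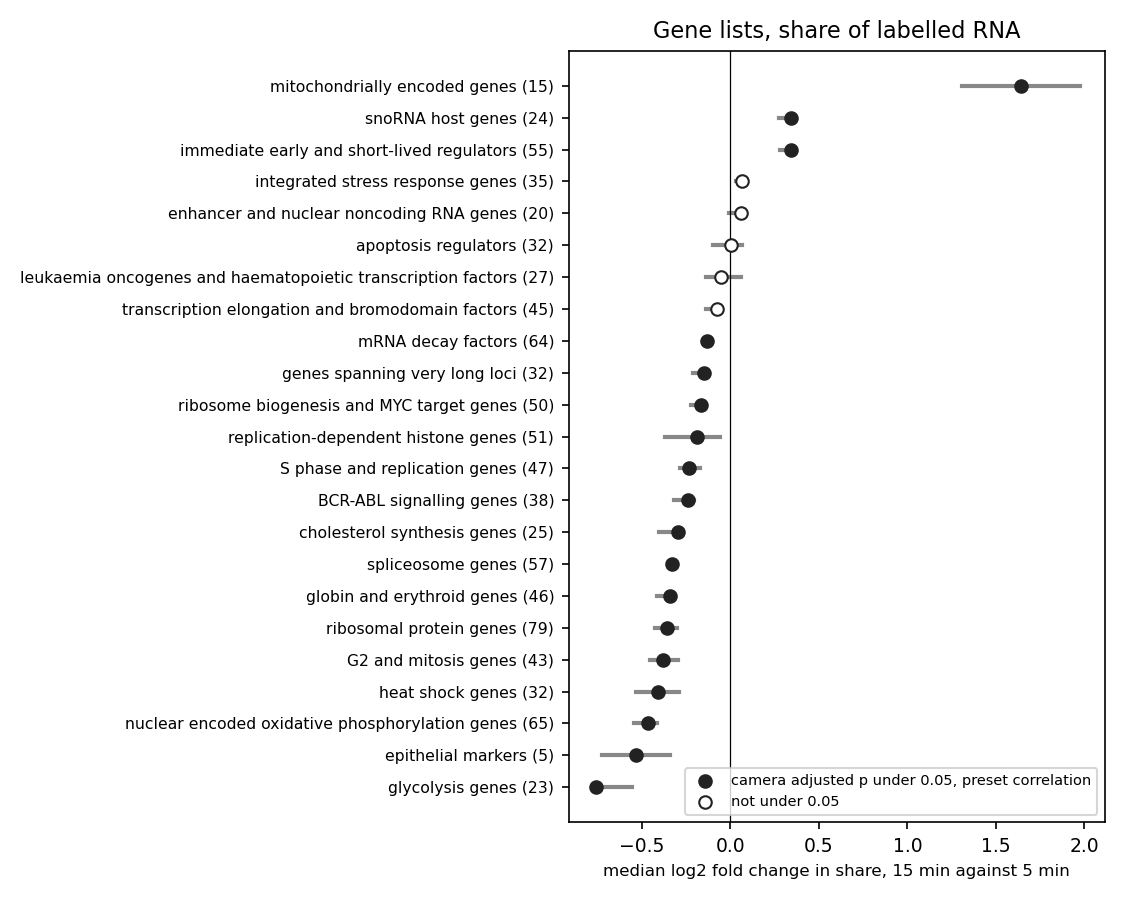
Median log2 fold change in share of the labelled RNA, 15 min against 5 min, for the 23 tested gene lists, with the number of measured members in brackets. Grey lines span the 4 pairings of a 15 min with a 5 min library, each centred on its median over genes, and filled points have a camera adjusted p under 0.05 with a preset correlation. Mitochondrially encoded genes lie highest, at 1.64, and glycolysis genes lowest, at -0.76, and under total-count scaling the medians of the transcription elongation and leukaemia lists turned positive.

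Markers of T cells, B cells, monocytes and fibroblasts gave few reads, and those of epithelial cells gave more. T cell markers summed to 66 and 68 reads after 15 min and to 86 and 80 after 5 min, over 13 genes. Monocyte and macrophage markers summed to 121, 108, 93 and 103 reads in the same order of libraries, B cell markers to 83, 73, 35 and 38, and fibroblast markers to 66, 76, 67 and 116. Epithelial markers summed to 1652 and 1656 reads after 15 min and to 1943 and 2280 after 5 min, most of them from the keratin genes KRT8 (124 ± 11.4 and 179 ± 15.4 CPM after 15 and 5 min) and KRT18 (109 ± 0.371 and 139 ± 11.5 CPM), which overlap on opposite strands. Of the 5 measured epithelial markers 4 fell and 0 rose (4 and 0 adjusted over the list alone). The median log2 fold change was -0.53 (camera adjusted p = 0.0167, adjusted p = 0.31 with an estimated correlation). The mean lay 0.53 below that of other genes. Without replicate 2 of the 15 min group it lay 0.84 below (adjusted p = 0.0103), and without replicate 2 of the 5 min group 0.23 below, where the call was lost (adjusted p = 0.12). Each of the other 4 marker lists had 2 measured members and was not tested as a list. CD3D among T cell markers (-0.68, lost with DESeq2 at an adjusted p of 0.126 and without replicate 1 of the 15 min or the 5 min group at 0.0545 and 0.103), LYZ among monocyte markers (-1.34, and -0.57 without replicate 2 of the 5 min group, where the call was lost at 0.472) and COL6A3 among fibroblast markers (-1.43) fell.

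The fourth comparison asked which genes had the highest and lowest deposited production rates, the quantity for which the series was made. The rate was highest for RN7SK, at 54.2, which was 7.37 times the next highest value and 13.1% of the sum over all genes. Mitochondrially encoded genes followed, with MT-CO1 at 7.36, MT-CYB at 6.70, MT-CO2 at 6.61, MT-ND6 at 5.45 and MT-ND4 at 5.19. HIST1H1C, a linker histone gene, had a rate of 4.86, and MT-ND5, MT-ND1 and MT-ATP6 had rates of 4.84, 4.47 and 4.28. The lowest rates among genes of moderate or high count were those of the zinc finger gene ZNF19 (1.81e-05), ATF7 (2.03e-05), AC104109.4 (4.68e-05), SHB (5.01e-05) and TFPI (5.86e-05). These are the authors' single values per gene, without replicates, and neither their scale nor their time unit is given in the sources used here.

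The table gave rates for 11777 genes, with a median of 0.0114, quartiles of 0.00374 and 0.0257, and 5th and 95th percentiles of 0.000384 and 0.0748. MYC had a rate of 0.37, 32.3 times the median, PIM1 a rate of 0.535, MCL1 a rate of 0.221 and MYB a rate of 0.108. Median rates were 4.66 for 12 mitochondrially encoded genes, 0.314 for 69 ribosomal protein genes, 0.256 for 21 replication-dependent histone genes and 0.175 for 20 snoRNA host genes. They were 0.0613 for spliceosome genes, 0.0465 for heat shock genes, 0.0438 for nuclear encoded oxidative phosphorylation genes, 0.0396 for immediate early and short-lived regulators, 0.0388 for glycolysis genes and 0.0362 for integrated stress response genes. Next came ribosome biogenesis and MYC target genes (0.0357), cholesterol synthesis genes (0.0335), G2 and mitosis genes (0.0333), S phase and replication genes (0.0302) and mRNA decay factors (0.0301). Transcription elongation and bromodomain factors had a median of 0.025, enhancer and nuclear noncoding RNA genes 0.0237, apoptosis regulators 0.0216, BCR-ABL signalling genes 0.0209 and globin and erythroid genes 0.0199. These 20 lists lay above the 97.5th percentile of 10000 random lists of the same size. Genes spanning very long loci, with a median of 0.00409 over 34 genes, lay at percentile 0.09, below the 2.5th percentile. Leukaemia oncogenes and haematopoietic transcription factors (0.0188, percentile 95.1) and epithelial markers (0.0138, percentile 60.9) lay between these limits. Against random lists matched on mean labelled count, 12 of the 23 lists lay outside the limits, with mitochondrially encoded, ribosomal protein, histone and snoRNA host genes all at percentile 100 and genes spanning very long loci at percentile 0. Of the 20 lists above the limit, 9 no longer were. These were BCR-ABL signalling genes (percentile 21.1), enhancer and nuclear noncoding RNA genes (31.0), transcription elongation factors (36.7), glycolysis genes (71.5) and ribosome biogenesis genes (88.3). The others were G2 and mitosis genes (95.4), S phase genes (96.0), cholesterol synthesis genes (96.8) and integrated stress response genes (96.9). The matching did not take exonic length into account. The rates followed counts per kilobase more closely (Spearman correlation 0.904) than uncorrected counts (0.806). Short or long transcripts alone could therefore place a list outside the limits, which was not tested.

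**Figure D4:**
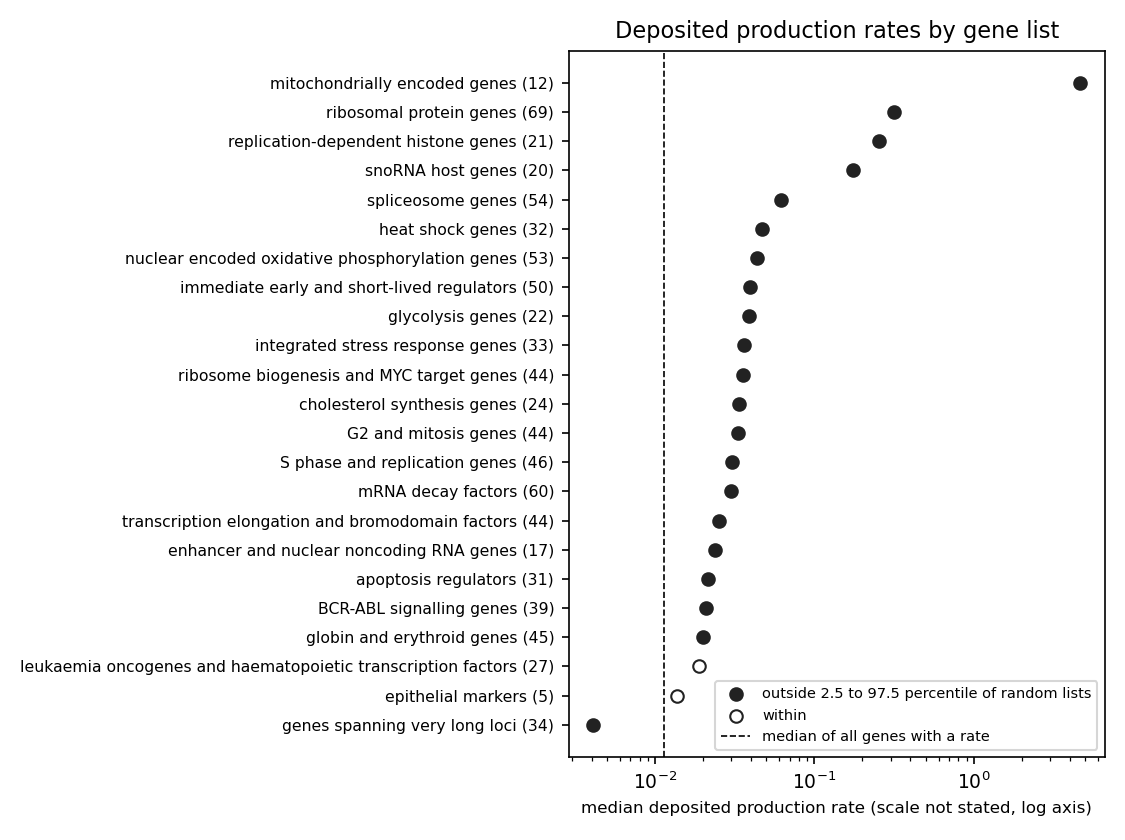
Median deposited production rate of each gene list on a log axis, with the number of members that have a rate in brackets. Filled points lie outside the 2.5th to 97.5th percentiles of random lists of the same size, and the dashed line is the median of all 11777 genes, 0.0114. Mitochondrially encoded genes lie highest, at 4.66, and genes spanning very long loci lowest, at 0.00409.

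The last comparison asked how the deposited rates relate to the deposited counts. Across 11687 genes, the Spearman correlation between the rate and the mean spike-in scaled count per kilobase of exon was 0.904 with the 15 min libraries and 0.908 with the 5 min libraries. Without a length correction it was 0.806, and over the 8753 of these genes with a mean count of at least 50 it was 0.852. These are correlations across genes, which are not independent replicates, so no p is given. RN7SK, first by rate, had 4607 and 8162 reads after 15 min and 24253 and 33087 after 5 min. HBG2 had a rate of 0.00443, at percentile 28, with 480 ± 76.0 CPM after 5 min. Of 849 tested genes with a mean count of at least 1000, 56 had no rate in the table, among them MT-CO3, SNHG3 and HNRNPA1.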

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

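Of the tests below, those of normalization and of carried-over RNA for the mitochondrial genes, of turnover for the genes that lost share, of pseudogenes outside coding genes, of nested features by class and of pseudogenes beside their own parents were chosen only after the result was seen.

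In the fly reads, which the comparisons use only as totals, 64 of 6340 tested fly genes differed in their share of the fly reads between label times (edgeR, 8 higher and 56 lower after 15 min), although the same kind of fly RNA was added to every sample. The smallest p was that of FBgn0013684, with 77 and 87 reads after 15 min against 541 and 495 after 5 min (log2 fold change -1.25). FBgn0013685 had 5 and 5 against 92 and 80, and FBgn0013680 had 7 and 7 against 73 and 87. FBgn0052368, with 29 and 17 against 24 and 25, was among the 8 higher. The fly identifiers were not paired with names, so these genes were not sorted into classes. Whether the human patterns weighed below share this difference between label times was therefore not tested. The median log2 fold change over fly genes was 0.01.

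The deposited table gave a rate for 49 genes that had no read in any of the 4 libraries, such as LRRC24 (0.00349), BUB1B-PAK6 (0.0033) and ZFP91-CNTF (0.00149). A further look showed 278 genes with a rate and fewer than 10 reads over the 4 libraries, 2.36% of the table.

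The first pattern weighed is the gain of mitochondrially encoded genes. For a shift of the scaling by the mitochondrial reads themselves, the median of the list stayed at 1.64 on the log2 scale with factors taken from the other genes. So few genes could hardly move these factors, so no conclusion is drawn from this. A single unusual library is argued against, since the lowest of the 4 pairings still gave 1.31. Unlabelled RNA carried through the enrichment would give at most 3-fold on the spike-in scale if labelled RNA rose in proportion to label time. The lowest pairing gave 7.10-fold. The median over all genes was already 3.20-fold, and 58.1% of genes lay above 3-fold. The gain of share thus largely fixed that outcome, so no conclusion is drawn from it. Slower entry of the label into mitochondria, a biological explanation, was neither supported nor excluded: 0 of the 13 protein-coding mitochondrial genes rose by less than 3-fold on the spike-in scale, but the gain of share itself fixes that outcome. Label entry was not measured.

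The second pattern is the loss of share by globin, ribosomal protein, glycolysis and nuclear oxidative phosphorylation genes, all abundant as mature mRNA. Differences in GC content or length are argued against as the whole cause, since removing their trends over protein-coding genes moved the pooled median of the 213 genes from -0.31 to -0.36. Turnover of labelled RNA within the label time would lower short-lived regulators at least as much. They instead lay above these lists by at least 0.65 on the log2 scale in all 4 pairings. A rise in their own synthesis between the label times was not measured and could give the same difference. Turnover is therefore neither supported nor excluded. Unlabelled mature RNA carried through the enrichment, which would weigh more after 5 min, may account for the pattern: features nested in host genes gained 0.56 on the log2 scale over those hosts (median of 607 pairs, 84.3% above the host, 0.46 to 0.59 over the 4 pairings), as it needs. For 309 pairs with a sense intronic gene the median was 0.37 (0.36 to 0.45), and for 298 with a processed pseudogene 0.69 (0.56 to 0.79), a class that gained share outside coding genes too. By class, the median was 0.28 for sense intronic genes, 0.34 for antisense genes and -0.08 for protein-coding genes. The paired difference may thus restate the gain of noncoding classes and is not separate support for carried-over RNA. Only 4 of these hosts are in the 4 lists, so the test bears on the pattern mostly through other genes, and no unlabelled control library was analysed here.

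The third pattern is the gain of processed pseudogenes and other genes of noncoding annotation. Low depth is argued against, since at an average log2 CPM of at least 3 processed pseudogenes lay 0.59 above protein-coding genes, and for pseudogenes of ribosomal protein genes, reads shared with parent genes are argued against, since their median was 0.49. Where the parent matched by symbol fell, the median of these pseudogenes was 0.50 (96 pseudogenes, 0.31 to 0.52 over the 4 pairings), with a median of -0.55 over their parents. Intronic reads of host genes counted at nested genes may contribute, since 1097 pseudogenes inside a protein-coding gene had a median 0.26 above that of 220 outside. For those outside, reads from introns of protein-coding genes are argued against as the cause, since these pseudogenes still lay at least 0.19 above protein-coding genes in all 4 pairings. Noncoding host genes were not examined. No biological explanation was tested.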

How the results depend on the processing

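The alternatives were chosen before the data were examined, except the medians of lists and gene types under total-count scaling. The ratio of labelled yield ran from 2.67 to 3.22 without each library in turn and from 2.79 to 3.20 under the other alternatives, within its SD. Of the counts of genes that changed in share, DESeq2 gave 3293 (923 higher and 2370 lower) against 6607 (2915 and 3692), and 921 and 2369 of its calls were shared. Of 3317 calls it did not make, 640 had no adjusted p and 2677 an adjusted p above the threshold, and the cause was not tested. Without each library in turn the count was 4729 to 5626, with 1729 to 2149 higher and 2934 to 3477 lower, in fits with fewer libraries, where the lone library was assumed to vary like the other group. No shared gene was called in the opposite direction under any of these settings. Whether the replicate numbers mark paired samples is not known. The deviations of same-numbered libraries had a correlation of 0.0487, which cannot settle this with 2 libraries per label time. The fit with a replicate block gave 6958 calls (3080 higher and 3878 lower), 16993 for accumulation and 18 lists. Spike-in scaled calls ran from 16510 to 17895 without each library in turn, and the median fold from 2.98 to 3.50, where 3.50 (without replicate 2 of the 5 min group) moved by more than the spread between pairings, the cause of which was not tested. Lists passing camera numbered 18 to 19 without each library in turn and 0 with an estimated correlation, which leaves few degrees of freedom, and fry lost the histone list (adjusted p = 0.197) and called the transcription elongation list (adjusted p = 0.0182), as did leaving out replicate 2 of either group (0.048 and 0.034). Camera's direction turned for lists that passed in neither fit, while differences in mean log2 fold change kept their sign. Without each library in turn these were -0.102 to -0.0102 for apoptosis regulators, -0.129 to -0.032 for integrated stress response genes and -0.122 to -0.056 for enhancer RNA genes. The median of protein-coding genes became 0.020 under total counts. Lists outside the limits for rates numbered 12 with matched random lists and 21 otherwise. The correlation of rates with counts was 0.901 and 0.904 without each 15 min library, 0.852 at a mean count of at least 50 and 0.806 with no length correction, and the cause was not tested.

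Of 117 named genes, 91 kept direction and call under all alternatives. Directions turned only for genes that did not pass in the main test. Under total counts, CRKL became 0.091, MCL1 0.083, NDUFA5 0.018 and NCL 0.0043 on the log2 scale, changes that the shift of the median of all genes covers. With a mean count of at least 50, CRKL became 0.056 and MCL1 0.048. Without each library in turn, values spanned 0 for PIM1 (-0.012 to 0.033), SNHG3 (-0.061 to 0.095), AFF1 (-0.041 to 0.061), CRKL (-0.0897 to 0.023), MCL1 (-0.101 to 0.024), MYB (-0.021 to 0.086), CD22 (-0.235 to 0.635) and THY1 (-0.249 to 1.08), and the causes were not tested. MIR17HG, not called in the main test, passed under total counts (adjusted p = 0.00397), with a mean count of at least 50 (0.0238) and with limma-voom (0.0279). MYB, also not called in the main test, passed under total counts (adjusted p = 0.0283). With no filter, MT-ATP6 and MT-ND5 missed the threshold (adjusted p = 0.101 and 0.114) at nearly the same fold. In simulated data with 2 libraries per label time, 23.9% of genes with the smallest simulated change were recovered. Only 200 of 16934 genes were changed there, whereas 6607 of 17322 passed in the real data. The adjustment is less strict when more genes change, so the simulated recovery does not give the share of small changes missed here.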

Other observations

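The tests of explanations are those weighed above, and the grouping by gene type and its medians under total-count scaling were chosen only after the main result was seen.

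By annotation, noncoding classes lay above protein-coding genes in their change of share between 5 and 15 min. Of 11547 protein-coding genes 1586 rose and 3519 fell, with a median log2 fold change of -0.08 (camera adjusted p = 1.78e-14, adjusted p = 0.113 with an estimated correlation). That median became 0.02 under total-count scaling, so its direction depends on the scaling. Of 1317 processed pseudogenes 354 rose and 20 fell (median 0.44), of 1541 antisense genes 393 rose and 35 fell (median 0.34), and of 136 snoRNA genes 36 rose and 4 fell (median 0.34), none of which passed with an estimated correlation (adjusted p = 0.117, 0.117 and 0.127). Long intergenic RNA genes had 129 higher and 46 lower of 766 (median 0.18, 0.29 under total-count scaling, adjusted p = 0.117 with an estimated correlation), and 136 small nuclear RNA genes had 6 higher and 8 lower (median 0.11, 0.22 under total-count scaling, adjusted p = 0.289, and 0.25 with an estimated correlation). Antisense and intronic genes cannot be separated from overlapping genes without the strand setting.

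Among the mitochondrial genes, those of the cytochrome oxidase subunits MT-CO1 and MT-CO3 had the smallest spike-in scaled folds of the protein-coding members, 4.85 and 4.30, although the 5 min libraries held them at 4196 ± 391 and 3518 ± 384 CPM (SD, n = 2), the highest levels of that group after 5 min. The other 11 lay between 7.75-fold for MT-CO2 and 12.5-fold for MT-ND2. These genes were compared after their values were seen, and the difference was not tested.

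RN7SK varied widely between libraries of a label time on the spike-in scale, with 1446 and 2642 reads per 100000 fly reads after 15 min and 2704 and 4116 after 5 min, and its highest value after 15 min was close to its lowest after 5 min. It had by far the highest deposited rate, 54.2, for an RNA whose labelled level did not rise with label time in these libraries.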
